A study of Arabidopsis thaliana with 4 samples.

How the data were processed

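The measurements are poly(A)+ RNA sequencing of Arabidopsis thaliana plants, accession Col-0, grown vertically for 7 days on agar medium without phosphate, per the labels' protocols. There were 4 libraries, 1 each of Col-0, hho2-1, phr1 and hho2phr1. The labels describe both single mutants as T-DNA insertion lines and hho2phr1 as the double mutant. They do not state which part of the plant was harvested. Libraries were made with the ScriptSeq v2 kit per the labels' protocols, and the series title calls them directional.

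The authors aligned reads with TopHat2 2.0.11 and quantified genes with Cuffdiff 2.2.1 on the TAIR10 build, per the submitters' processing notes. The library type, annotation release, treatment of multiply aligned reads and method of scaling between libraries were not stated. The deposited values are FPKM, fragments scaled by transcript length and library size, given by the authors for each gene and library with a 95% confidence interval in FPKM and a quantification status (OK or FAIL), per the file headers. The authors' spread model behind the interval is not stated, and with 1 library per genotype it does not hold variation between plants. The 4 sets of value columns were matched to genotypes by their names: WT to Col-0, and dbl to hho2phr1.

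The table held 33557 genes, of which 33278 were nuclear and 279 organellar. Of these, 32810 matched the TAIR10.1 reference annotation, which was used here for names, gene types and exon lengths. Some symbols belong to more than 1 gene, so every value was looked up by locus identifier: PHR1 here is AT4G28610, BAT1 is AT4G31910 and PS2 is AT1G73010. In the table, 4249 genes share a locus interval with another gene, so their values depend on how the authors' tool divided the reads. Values of near-identical paralogs, such as the LHCB1 and PHT1;1 to PHT1;3 genes, carry the same limit. The status was FAIL in at least 1 library for 8 genes.

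The files give no read counts. The depth was estimated from 251 genes with low values, where FPKM times exon length steps by whole fragments. It was 48100000 fragments for Col-0, 45000000 for hho2-1, 39500000 for phr1 and 40700000 for hho2phr1. This is the library size behind the FPKM values, not a count of reads in the files. Between 97.9% and 98.3% of the ratios of low values between libraries were ratios of small whole numbers, within a tolerance of 0.3%. In Col-0, 1 fragment on a transcript of 1 kilobase gives 0.0208 FPKM. The authors' interval spans 22.8% of the value to each side at the median gene with FPKM of at least 10. On genes shorter than 200 nucleotides, such as microRNA precursors, a few fragments give a high FPKM, and the authors' lower bound is then 0.

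Differences are between 2 libraries on the scale of log2(FPKM + 1). This pseudocount of 1 shrinks the differences of genes with low values, so a stated log2 difference understates their fold. Genes with FPKM of at least 1 in either library were compared, and a difference of at least 1 on that scale was counted as 2-fold. With 1 library per genotype, no p-value or standard deviation between replicates can be given for these 5 comparisons. For each of them, 100 data sets of unchanged genes were simulated from the authors' intervals, and the mean number of 2-fold genes is given beside the count. Overlaps of the same allele's effect in 2 backgrounds were set beside n1 x n2 / N, the number that independent lists would share, and beside the same simulation.

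The 4 genotypes form a factorial of 2 alleles. A secondary analysis fitted both alleles to all 4 libraries with limma 3.58.1 in R 4.3.3 (intensity trend, Benjamini-Hochberg adjusted p of 0.05) on 20650 genes. The 1 residual degree of freedom is the failure of the allele effects to add, so its error is not one between replicates. The third split, Col-0 and hho2phr1 against hho2-1 and phr1, needed a fit of its own. Its residual is the hho2 effect, so its error differs from that of the allele counts, and its count cannot be ranked against theirs. On data simulated from these libraries, limma found 67% of 100 genes set to 2-fold and 100% of 100 genes set to 4-fold, and called 0.411% of 20450 unchanged genes, 84 genes. In 20 simulated data sets with no changed gene, a test added after the data had been seen, limma called 27.4 genes on average for phr1, 30.2 for hho2 and 26 for the third split. The draws used the authors' intervals as their spread, and the adjusted p did not hold its rate on them. The size call in 1 background found 37% and 100% of the same genes and called 1.32% of the unchanged ones.

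Before the data were examined, 23 gene lists with 315 genes, the rule for named genes, the tests and their alternatives were fixed, except where a choice is said to have been made later. The lists covered the targeted gene families, phosphate signalling, phosphate transport, phosphatases, membrane lipids, anthocyanin, nitrate, iron, sulfur, zinc, root hairs, root meristem, jasmonate, salicylate, glucosinolates, abscisic acid, senescence, heat shock, touch, the clock, photosynthesis, the endodermis and reference genes. Of the list genes, 300 had the listed symbol in the table or the reference, 3 had another name there and 12 had none. A list's median over members with FPKM of at least 1 in any library is given with its percentile among 10000 random lists of like size, matched on expression decile. This describes these libraries only. The random lists draw genes independently, whereas members of a fixed list can vary together, so an extreme percentile is not a test of an allele.

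The named genes are HHO2 and PHR1, and for each comparison the 8 highest and 8 lowest nuclear genes with FPKM of at least 5, status OK, intervals apart and a 2-fold difference. Up to 4 members of each list with the largest differences, and the 5 highest and 5 lowest departures from additivity, were added. Genes that passed limma, and others said to have been chosen later, are named besides. The value of 1 list member is not reported here.

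The alternatives were pseudocounts of 0.1 and 5, no filter on low values, FPKM of at least 5, rescaling by the median of ratios or to equal sums, status OK, 1.5-fold and 4-fold thresholds, intervals apart, limma without a trend, and random lists that were not matched. One alternative was added after the data had been seen: genes whose authors' lower bound was above 0 in at least 1 of the 4 libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.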

Results

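The series measured gene expression in phosphate-deprived Arabidopsis of 4 genotypes: the wild type Col-0, the single mutants hho2-1 and phr1, and the double mutant hho2phr1. HHO2 encodes a transcription factor of the GARP family related to HRS1, and PHR1 encodes the MYB-related transcription factor that activates many genes under phosphate starvation. With 1 library per genotype, no difference between 2 libraries has a replicate check. Estimated depths were 48100000 fragments for Col-0, 45000000 for hho2-1, 39500000 for phr1 and 40700000 for hho2phr1. Between 20045 and 20091 genes had an FPKM of at least 1 in each library. The metallothionein gene MT1A held 13.1%, 11.2%, 17.2% and 13.6% of all FPKM in Col-0, hho2-1, phr1 and hho2phr1. Correlations between libraries across genes lay between 0.977 and 0.987, where genes are not independent replicates.

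The targeted genes were both lower in their mutants. PHR1 (AT4G28610, TAIR10 chromosome 4, 14132856 to 14135259) stood at 37.7 FPKM in Col-0 and 43.2 in hho2-1, against 7.54 in phr1 and 6.5 in hho2phr1. The authors' 95% intervals were 29.6 to 45.9 in Col-0 and 5.49 to 9.6 in phr1. HHO2 (AT1G68670, chromosome 1, 25782029 to 25784076) stood at 90.7 FPKM in Col-0 and 81.2 in phr1, against 59.8 in hho2-1 and 51.8 in hho2phr1. Its level in hho2-1 was thus 0.659 times that in Col-0, and the intervals of 71.9 to 109.6 and 47.2 to 72.5 overlapped. In hho2phr1 it was 0.638 times that in phr1. Gene totals do not show where the transcript ends relative to the insertion, whose position is not in the labels. HHO3, a close relative of HHO2, was higher with the hho2 allele, at 186 FPKM in hho2-1 against 111 in Col-0 and at 149 in hho2phr1 against 107 in phr1. Among the 20 expressed genes nearest to HHO2, with FPKM of at least 1 in any library, 0 differed 2-fold with the hho2 allele in either background. The largest difference was 0.57. Of the 20 expressed genes nearest to PHR1, 1 differed 2-fold with the phr1 allele: CRU3, by -1.53 in phr1 against Col-0 but by 0.47 in hho2phr1 against hho2-1.

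**Figure D1:**
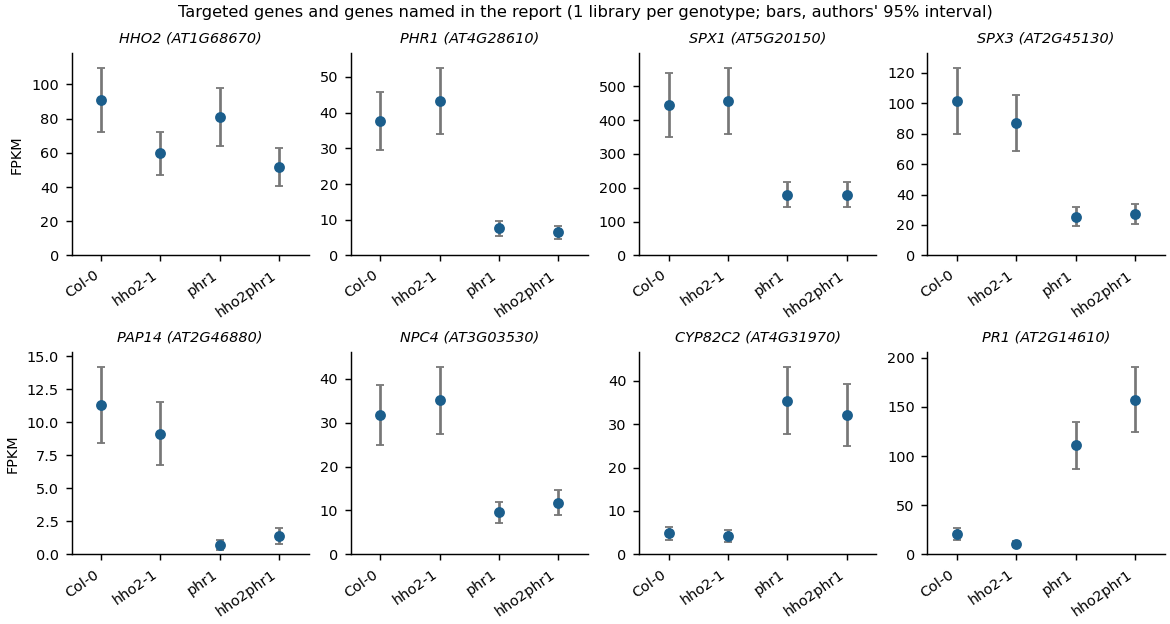
FPKM of HHO2, PHR1 and 6 further genes in the 4 libraries, 1 point per library with the authors' 95% interval as the bar. PHR1 lies at 7.54 and 6.5 FPKM in the libraries with the phr1 allele against 37.7 and 43.2 in the others, while HHO2 lies at 59.8 and 51.8 in the libraries with the hho2 allele against 90.7 and 81.2 in the others.

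The first comparison, phr1 against Col-0, shows what differed without full PHR1 function in plants grown without phosphate. Genes of the phosphate starvation response were lower in phr1. SPX3, which encodes a phosphate-sensing SPX protein, was at 25.5 FPKM against 101.5 in Col-0, a log2 difference of -1.95. SPX1, an inhibitor of PHR1, was at 180 FPKM against 444. The acid phosphatase gene PAP14 was at 0.746 FPKM against 11.3 (log2 -2.82), and NPC4, a phospholipase of membrane lipid turnover, was at 9.59 against 31.7 (log2 -1.63). CYP82C2, a cytochrome P450 of indolic defence compounds, stood out in the other direction, at 35.4 FPKM against 4.84 (log2 2.64).

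By list, all 15 measured genes of membrane lipid remodelling were below Col-0 in phr1, with a median of -0.40, lower than in all 10000 matched random lists. Of these, 4 were 2-fold lower: NPC4, the sulfolipid synthase SQD2 (185 to 78.5 FPKM), the galactolipid synthase MGD3 (74.8 to 36.3) and the phosphodiesterase GDPD6 (2.01 to 0.072). Among 17 genes of phosphatases and ribonuclease, 16 were below Col-0 and 5 were 2-fold lower, with a median of -0.48 (percentile 0). PAP23 differed by -1.65, PAP5 by -1.49 and PAP24 by -1.37. In the SPX, IPS1 and microRNA precursor list, 6 of 13 were 2-fold lower, 3 of them with intervals apart, and the median was -0.65 (percentile 0). The noncoding RNA IPS1 was at 242 FPKM against 544, whereas its relative AT4 was at 2120 against 1959. MIR399B and MIR399D were listed at 0 in phr1, but their authors' lower bound was 0 in every library, as was that of MIR399C and MIR399F. The medians of this list, here and below, thus rest in part on precursors of few fragments.

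Phosphate transport genes had a median of -0.20 in phr1 (percentile 0). Of 17, 3 were 2-fold lower: PHT1;7 by -1.2, PHT1;9 by -1.14 and PHT1;2 by -1.04. PHT1;4, a main root phosphate transporter, was at 149 FPKM against 145. The 13 sulfur starvation genes were all below Col-0, with a median of -0.41 (percentile 0), though 0 were 2-fold lower; the largest was BGLU28, at 3.01 FPKM against 5.90. Senescence genes had a median of -0.34 (percentile 0.01), with SAG12 at 1.04 FPKM against 6.25 and SAG13 higher, at 20.5 against 11.4.

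Defence-related lists were higher in phr1. PR1, a salicylate marker, was at 111 FPKM against 20.8 (log2 2.36), and the salicylate list had a median of 0.16 (percentile 99.5). Jasmonate genes had a median of 0.18 (percentile 99.9), with LOX4 higher by 0.88 and LOX3 by 0.61. Heat shock genes, which can respond to handling, had the highest list median, 0.76 (above all 10000 random lists), with HSP70 at 33.4 FPKM against 14.4. Photosynthesis genes had a median of -0.12 (percentile 0.07), endodermis genes -0.23 (percentile 0.04), clock genes -0.15 (percentile 0.74) and abscisic acid genes -0.11 (percentile 2.49). The lists of anthocyanin, nitrate, iron, zinc, root hair, root meristem, glucosinolate, touch, reference and targeted family genes had medians between -0.08 and 0.14, inside the middle 95% of random lists.

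Among single genes, BAT1, an acyltransferase gene linked to brassinosteroid inactivation, was at 12.9 FPKM in phr1 against 95.5 in Col-0 (log2 -2.79). AT5G17340 was at 4.25 FPKM against 25.7. CYP71A13, an enzyme of camalexin synthesis, was at 32.9 FPKM against 5.28. AT3G01345 was at 15.6 FPKM in phr1 and between 0.221 and 0.331 in the other libraries. CPuORF25, which shares its interval with another gene, was at 17 FPKM in phr1 and at most 0.054 elsewhere. HEI10, a meiotic crossover gene, was at 1.4 FPKM against 30.9, and MRD1, which shares its interval, at 0.081 against 10.1; both were lower in each mutant than in Col-0. In all, 157 genes were 2-fold higher and 117 lower among 20323, against 110.2 and 111.1 in simulated unchanged libraries. With the authors' intervals apart, 86 were higher and 44 lower.

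The second comparison, hho2-1 against Col-0, shows what differed with the hho2 allele where PHR1 was intact. Genes of the phosphate starvation response differed little. SPX1 was at 456 FPKM in hho2-1 and 444 in Col-0, SPX3 at 87.0 and 101.5, and PAP14 at 9.16 and 11.3. IPS1 was lower, at 384 FPKM against 544. Of genes away from phosphate, QQS, a regulator of carbon and nitrogen allocation, was at 12.6 FPKM against 73.9 (log2 -2.46). AT2G43240 was at 0.745 against 10.5 (log2 -2.72).

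The 4 phosphate lists had medians between -0.10 and 0.03, all inside the middle 95% of random lists. For phosphate transport the median was -0.10 (percentile 4.96), and 0 of 17 members were 2-fold different. Of 13 signalling genes, MIR827 was higher by 1.92 and MIR399C lower by -1.17, both on precursors shorter than 200 nucleotides whose intervals overlapped. The targeted families had a median of 0.19 (percentile 99.9), with HHO3 higher by 0.74, HHO4 by 0.48 and HHO6 by 0.40.

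Other lists differed more in hho2-1. Endodermis genes had a median of -0.35 (below all 10000 random lists), with the aquaporin TIP2;3 at 6.75 FPKM against 14.8. Touch and wounding genes had a median of -0.38 (percentile 0.01), with CBF2 at 1.02 FPKM against 4.89. Abscisic acid genes had a median of -0.23 (percentile 0.02), with RD29A at 7.35 FPKM against 12.1. The salicylate list had a median of -0.16 (percentile 0.22), with PR1 at 10.5 FPKM against 20.8, and the jasmonate list -0.15 (percentile 0.37), with JAZ7 lower by -0.75. Photosynthesis genes were higher, by 0.18 at the median (above all 10000 random lists), and heat shock genes by 0.24 (percentile 98.7), with HSP70 at 25.1 FPKM against 14.4. The clock genes CCA1 and LHY were lower by -0.67 and -0.63, with a list median of -0.13 (percentile 2.86). Lists of anthocyanin, nitrate, iron, sulfur, zinc, root hair, root meristem, glucosinolate, senescence and reference genes had medians between -0.06 and 0.07, inside the middle 95%. All 11 reference genes were below Col-0, with a median of -0.056. That median was at percentile 51.3 of the matched random lists, so genes of like expression shared this shift.

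Seed storage transcripts were among the highest single genes in hho2-1. The cruciferin genes CRU3 and CRA1 were at 28.7 and 21.6 FPKM, against 4.84 and 4.53 in Col-0. BGLU19, which shares its interval with another gene, was at 14.2 against 3.29, and the oleosin OLEO2 at 8.09 against 2.71. DIN11 was at 17.2 FPKM against 5.37, and BGLU28 at 14.3 against 5.90. SAG12, a senescence protease, was at 1.04 FPKM against 6.25, and the thionin THI2.2 at 2.68 against 11.9. In all, 85 genes were 2-fold higher and 94 lower among 20341, fewer than the 112.4 and 111.4 of simulated unchanged libraries. With intervals apart, 17 were higher and 18 lower.

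The third comparison, hho2phr1 against hho2-1, asks for the effect of the phr1 allele where HHO2 was already reduced. The phosphate genes were lower here too. SPX3 was at 27.1 FPKM in hho2phr1 against 87.0 in hho2-1, SPX1 at 179 against 456, and PAP14 at 1.39 against 9.16 (log2 -2.09). NPC4 was at 11.8 FPKM against 35, and PHT1;2 at 2.44 against 11 (log2 -1.80). PR1 was at 157 FPKM against 10.5 (log2 3.79).

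All 15 lipid genes were below hho2-1 again, with a median of -0.38 (percentile 0). The signalling list had a median of -1.34, with 7 of 13 genes 2-fold lower, 3 of them with intervals apart, and the phosphatase list -0.34, with 14 of 17 below 0 (both percentile 0). Of 17 transport genes 4 were 2-fold lower, with a median of -0.16 (percentile 1.42). PHO1;H1, a phosphate exporter, differed by -1.35, PHT1;7 by -1.28 and PHT1;9 by -1.17. Sulfur genes had a median of -0.16 (percentile 2.27), with BGLU28 lower by -1.34, and senescence genes -0.28 (percentile 0.85), with SAG13 higher by 1.59. All 12 root hair genes were below hho2-1, with a median of -0.28 (percentile 0.41). The targeted families had a median of -0.20 (percentile 1.23), with HHO1 lower by -0.76.

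Salicylate genes had a median of 0.72 and touch genes one of 0.65, both above all 10000 random lists, with WRKY38 higher by 1.1, ZAT12 by 1.23 and ZAT10 by 1.01. Abscisic acid genes had a median of 0.40 (percentile 99.99), endodermis genes 0.35 (percentile 99.99), photosynthesis genes 0.26 (percentile 99.96), jasmonate genes 0.25 (percentile 99.9) and nitrate genes 0.23 (percentile 99.7). VSP2 was at 66.4 FPKM against 24.3, and the nitrate reductase NIA2 was higher by 0.58. The remaining 7 lists, of anthocyanin, iron, zinc, root meristem, glucosinolate, heat shock and clock genes, lay inside the middle 95%, as did the reference genes, whose 11 members were all above 0 with a median of 0.12, or 0.009 after rescaling to equal sums. Outside the lists, BAT1 differed by -2.15, the lipid transfer gene LTP4 by 3.37 and AT4G12490 by 3.05. In all, 259 genes were 2-fold higher and 147 lower among 20456, against 112.5 in each direction in simulated libraries. After rescaling to equal sums, which shifts the median of all genes by -0.10, the split was 209 higher and 215 lower.

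The fourth comparison, hho2phr1 against phr1, asks for the effect of the hho2 allele where PHR1 was already reduced. Phosphate genes stayed near their level in phr1, with SPX1 at 179 FPKM against 180, SPX3 at 27.1 against 25.5 and NPC4 at 11.8 against 9.59. IPS1 was at 145 FPKM against 242 (log2 -0.73), AT4 at 1560 against 2120 (log2 -0.44) and PHT1;2 at 2.44 against 4.90 (log2 -0.78). Photosynthesis genes were all higher: 20 of 20, with a median of 0.54. LHCB1.1, a light-harvesting protein gene, was at 294 FPKM against 106 (log2 1.46), and LHCB3 at 617 against 347.

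The signalling list had a median of 0.00 and the lipid list one of 0.05, both inside the middle 95%, while the transport median was -0.14 (percentile 1.0). Of the 13 signalling genes, 5 were above phr1 and 6 below, with a mean of -0.289. Their median falls on genes with no difference, MIR399B and MIR399D, which were listed at 0 in phr1. It thus sits at the floor and does not measure a lack of change. Phosphatase and ribonuclease genes had a median of 0.11 (percentile 98.8), with the ribonuclease RNS1 at 46.6 FPKM against 25.1. Sulfur genes were higher, with 11 of 13 above phr1 and a median of 0.22 (percentile 99.99), and nitrate genes had 14 of 16 above, with a median of 0.18 (percentile 99.96). NRT2.5 differed by 0.86 and NRT2.1 by 0.62. The medians of salicylate genes (0.25), abscisic acid genes (0.21), touch genes (0.20) and endodermis genes (0.14) lay above the middle 95%, with COR15A at 3.03 FPKM against 0.722. Root hair genes had a median of -0.15 (percentile 1.56). The lists not named here, with anthocyanin at -0.10, heat shock at -0.15 and senescence at 0.15, lay inside the middle 95%.

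CRU3 and CRA1 were at 40.1 and 37.2 FPKM in hho2phr1, against 1.02 and 1.31 in phr1. OLEO2 was at 7.02 against 0.530, and LEA18, of the late embryogenesis abundant class, at 6.95 against 1.07. QQS was at 11.5 FPKM against 40.4 and AT2G43240 at 0.792 against 9.92. In all, 129 genes were 2-fold higher and 96 lower among 20353, against 111.2 and 113 in simulated libraries. With intervals apart, 51 were higher and 27 lower.

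The fifth comparison, hho2phr1 against Col-0, holds both alleles at once. Phosphate genes were lower, immune and photosynthesis genes higher. PAP14 differed by -2.37, SPX3 was at 27.1 FPKM against 101.5, PHT1;2 differed by -1.82 and IPS1 was at 145 FPKM against 544. PR1 was at 157 FPKM against 20.8 (log2 2.86) and LTP4 at 21.3 against 2.15 (log2 2.82).

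The signalling list had a median of -1.30 and the phosphatase list -0.39, with 7 of 13 and 3 of 17 members 2-fold lower. Of the 7 signalling genes, 3 had intervals apart, and MIR399B, MIR399C, MIR399D and MIR399F had an authors' lower bound of 0 in every library. Transport genes had a median of -0.30, with 6 of 17 2-fold lower, among them PHT1;9 by -1.53, PHT1;8 by -1.19 and the glycerol-3-phosphate transporter G3Pp3 by -1.15. All 15 lipid genes were lower, with a median of -0.24 (percentile 0.01) and GDPD6 at -1.49. All 20 photosynthesis genes were above Col-0, with a median of 0.35, and the medians of salicylate genes (0.45), heat shock genes (0.73), jasmonate genes (0.29) and nitrate genes (0.26) were likewise above all 10000 random lists. VSP2 was higher by 1.23, WRKY38 by 1.19, HSP17.4 by 1.46, on a shared interval, and the nitrate reductase NIA1 by 0.70. Glucosinolate genes had a median of -0.17 (percentile 0.12), with CYP79F1 at 17.1 FPKM against 33.5. Abscisic acid genes had a median of 0.18 (percentile 99.55), zinc genes 0.17 (percentile 97.7), root hair genes -0.15 (percentile 1.84), sulfur genes -0.16 (percentile 0.77) and senescence genes -0.17 (percentile 2.28). Lists of anthocyanin, iron, root meristem, touch, clock, endodermis, reference and targeted family genes lay inside the middle 95%. In all, 258 genes were 2-fold higher and 132 lower among 20400, against 114.3 and 116.2 in simulated libraries.

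**Figure D2:**
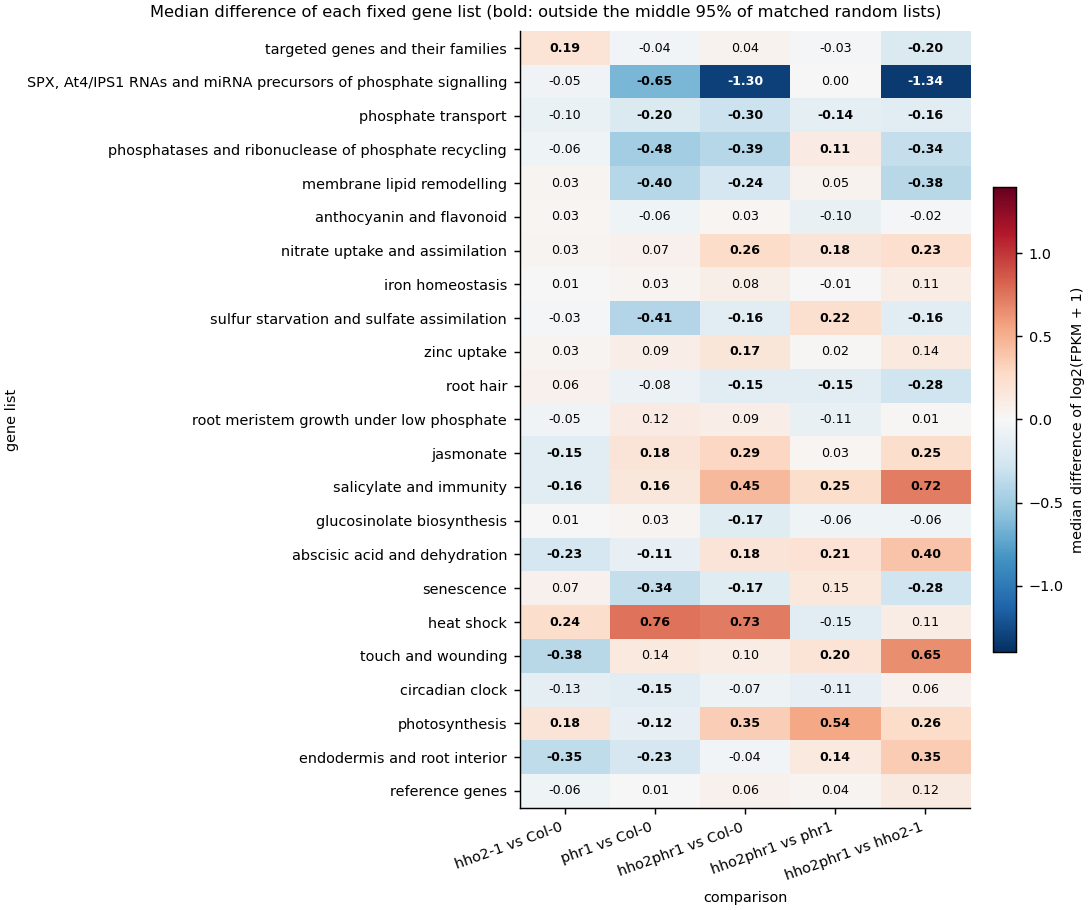
Median difference of log2(FPKM + 1) for each of the 23 gene lists (down the map) in the 5 comparisons (across), with colour from lower in blue to higher in red and bold values outside the middle 95% of 10000 matched random lists. The signalling list reads -0.65, -1.30 and -1.34 where the libraries differ in the phr1 allele, and -0.05 and 0.00 where they differ in the hho2 allele alone. The 0.00, in hho2phr1 against phr1, falls on genes at the floor, and the mean of the list there is -0.289. The list holds microRNA precursors of few fragments, which enter every one of its medians.

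Fitting both alleles to all 4 libraries with limma gave 31 genes that rose and 17 that fell with the phr1 allele, at an adjusted p of 0.05 (1321 and 995 unadjusted). In 20 simulated data sets with no changed gene, limma called 4 to 79 genes for this allele, with at most 1090 unadjusted, so the number that passed lies inside the range without change and the unadjusted number above it. On genes with a lower bound above 0, a choice made after seeing the data, limma gave 77 higher and 27 lower, 104 in all, against 5 to 102 in the simulation. CYP82C2 rose by 2.63 (SE 0.10, adjusted p = 0.0074) and the transporter gene AT2G04050 by 2.32 (adjusted p = 0.0094). ARD3, of methionine salvage, rose by 2.08 and the glutathione transferase gene GSTF7 by 1.2 (adjusted p = 0.039). BAT1 fell by 2.47 (adjusted p = 0.023), PHR1 by 2.37 (adjusted p = 0.017), PAP14 by 2.45 (adjusted p = 0.040), SPX3 by 1.80 (adjusted p = 0.019), SPX1 by 1.32 (adjusted p = 0.030), NPC4 by 1.56 (adjusted p = 0.019) and IPS1 by 1.28 (adjusted p = 0.040). OCT1, an organic cation transporter gene, fell by 1.62 (adjusted p = 0.019). Of the phr1 genes, 5 of the 31 and 4 of the 17 had an authors' lower bound of 0 in every library. The total of 48 depended on settings: limma gave 10 without an intensity trend, 13 after rescaling to equal sums, with the majority turned to 5 higher and 8 lower (668 and 2268 unadjusted), and 0 without a filter on low values (1411 higher and 1006 lower unadjusted).

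Over all genes, limma called 5 of 13 signalling genes, 0 of 17 transport genes, 1 of 17 phosphatase genes and 1 of 15 lipid genes lower with the phr1 allele. Of the 5 signalling genes, MIR399B and MIR399D rest on a few fragments, with an authors' lower bound of 0 in every library. Adjusted over the list alone, the counts were 8, 6, 11 and 10, all lower. The sulfur list gave 0 over all genes and 5 lower when adjusted over the list alone, and the salicylate list 0 and 4 higher. Glucosinolate genes gave 0 over all genes, with 2 higher and 6 lower when adjusted over the list alone. For touch genes the counts were 0 and 4 higher, for jasmonate genes 0 and 2 higher, for senescence genes 0, then 1 higher and 3 lower, and for iron and heat shock genes 0 and 1 higher each. The targeted families gave 1 lower, PHR1, by either count. The other 10 lists gave 0 by either count for the phr1 allele.

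For the hho2 allele limma called 3 genes higher and 5 lower, with 480 and 483 at an unadjusted p under 0.05. Simulated data without change gave 4 to 75 and a mean of 984 unadjusted. Of these 8 genes, 7 were called on a few fragments, with an authors' lower bound of 0 in every library. The remaining gene, AT2G43240, fell by 2.66 (SE 0.14, adjusted p = 0.018). HHO2 had an adjusted p of 0.44 in limma. Adjusted over the list alone, 1 targeted family gene was higher and 1 lower, 1 signalling gene and 1 clock gene were lower, 1 sulfur gene was higher, and 2 senescence genes were higher and 1 lower, all with 0 over all genes. The other 18 lists gave 0 by either count. The third split, which no single allele makes and whose fit has another error, gave 0 higher and 1 lower in limma (742 and 415 unadjusted). Together its unadjusted genes also exceed the highest number simulated without change for this split, 1063. Such an excess is therefore not particular to the phr1 allele. Adjusted over the list alone, the third split gave 1 salicylate and 2 touch genes lower.

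Across backgrounds, 71 genes were 2-fold higher and 31 lower with the phr1 allele both in phr1 against Col-0 and in hho2phr1 against hho2-1, which share no library. Independent lists would share 1.49 and 0.491 genes, and simulated unchanged libraries gave 20.4 and 20.1. For the hho2 allele the shared genes were 23 higher and 19 lower, against 0.26 and 0.254 for independent lists and 20.2 and 20.3 in simulated unchanged libraries. Among the shared hho2 genes were CRU3, CRA1, QQS and AT2G43240. Genes called in opposite directions in the 2 backgrounds numbered 10 of those higher and 10 of those lower in the wild-type background, for either allele. The spread simulated for hho2-1 against Col-0 exceeded the observed one, as given below, so the simulated hho2 overlap can run high. With intervals apart, the hho2 overlap was 10 higher and 4 lower and that of phr1 was 53 and 21. Across genes with FPKM of at least 10, the effects correlated at 0.39 between backgrounds for phr1 (13316 genes) and 0.177 for hho2 (13322 genes), where genes are not independent replicates.

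**Figure D3:**
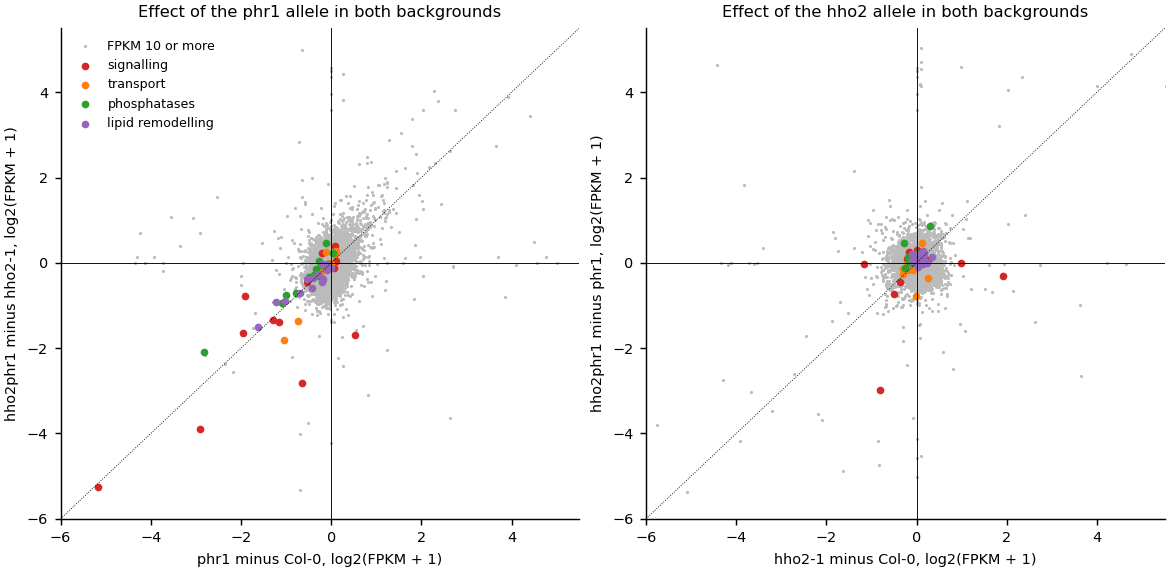
Effect of the phr1 allele (left) and the hho2 allele (right) on each gene with FPKM of at least 10 in any library, as a difference of log2(FPKM + 1), with wild-type background on the horizontal axis and mutant background on the vertical axis. Coloured points are the 4 phosphate lists, and the dotted line marks equal effects. SPX3 differs by -1.95 and -1.65 on the left, and the correlation is 0.39 on the left and 0.177 on the right.

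The hho2-1 and phr1 differences share the Col-0 library. Across 13342 genes they correlated at 0.195, against 0.498 in unchanged libraries simulated from the authors' intervals, with a covariance of 0.016 against 0.0482. Opposite effects of the alleles would lower both values, and an equal spread of any size gives a like correlation. They therefore do not show how wide the intervals were. Across the same genes, the differences of hho2-1 from Col-0 had a standard deviation of 0.277, against 0.31 simulated. For phr1 against Col-0 it was 0.297 against 0.307. For hho2phr1 against Col-0, hho2-1 and phr1 it was 0.346, 0.371 and 0.315, against 0.298, 0.315 and 0.306 simulated. An observed difference holds noise and any effect, so the simulated spread ran high for hho2-1 against Col-0. Fewer genes than simulated were also 2-fold there, 85 and 94 against 112.4 and 111.4. For phr1 against Col-0 the gap was small. In the comparisons with hho2phr1 effects could add to the observed spread, so whether the simulated numbers run high there was not settled. The departure of hho2phr1 from adding both single-mutant differences was 2-fold or more for 203 genes upward and 183 downward, against 270.6 and 276.3 simulated. HEI10 and MRD1 departed by 3.54 and 3.74, since they were low in every mutant. THI2.2 departed by 2.4, at 13.6 FPKM in hho2phr1 against 2.68 in hho2-1. Downward, CPuORF25 and AT3G01345 departed by -4.14 and -3.58, both high in phr1 alone.

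**Figure D4:**
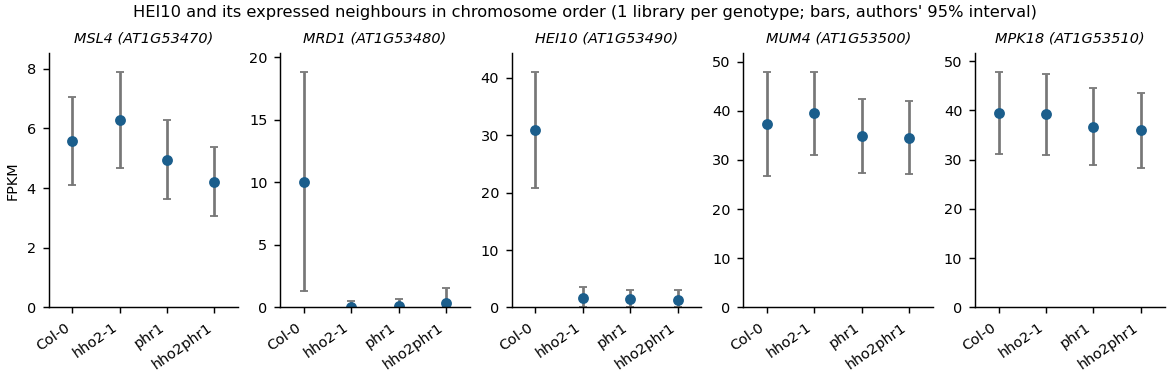
FPKM of HEI10, MRD1 and the nearest expressed genes on chromosome 1 in the 4 libraries, 1 point per library with the authors' 95% interval as the bar. HEI10 lies at 30.9 FPKM in Col-0 and between 1.38 and 1.73 in the mutants, while MUM4 lies between 34.5 and 39.5 in all 4.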

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

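The test of the root share was chosen only after the result had been seen; those of library scaling and the hour of harvest were written before theirs. Opposite directions of an allele's effect in the 2 backgrounds were picked out for a closer look, and with 1 library per genotype none of these differences was tested.

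With the hho2 allele, 4 lists whose medians lay outside the middle 95% of random lists in both backgrounds were below 0 in hho2-1 against Col-0 and above 0 in hho2phr1 against phr1. They were -0.16 and 0.25 for salicylate genes, -0.23 and 0.21 for abscisic acid genes, -0.38 and 0.20 for touch genes, and -0.35 and 0.14 for endodermis genes. With the phr1 allele, by the same limit, medians were below 0 in phr1 against Col-0 and above 0 in hho2phr1 against hho2-1 for 3 lists: -0.11 and 0.40 for abscisic acid genes, -0.12 and 0.26 for photosynthesis genes, and -0.23 and 0.35 for endodermis genes. Against random lists that were not matched, the endodermis median in hho2phr1 against phr1 (percentile 97.35) and the abscisic acid median in phr1 against Col-0 (percentile 2.59) came inside the middle 95%. Both sets rest on the same 4 libraries and the same departure from additivity. The noncoding RNA gene AT3G41761 differed by 2.62 and -1.39 with the hho2 allele, and was listed at 0 in Col-0. AT2G12905, an open reading frame of few fragments, differed by -1.39 and 2.15.

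Photosynthesis genes were higher in hho2phr1 than in phr1, 20 of 20, with a median of 0.54. Rescaling the libraries left the median at 0.545 or more, which argues against library scaling. A smaller share of root tissue would lower root markers together, and it stays open: the endodermis list was at 0.14, with a spread that reaches -0.08, and the root hair list at -0.147. For a different hour of harvest, morning genes minus evening genes gave -0.457, with medians of -0.348 and 0.109. By the rule written before, a difference under 0.5 in size counts against this explanation. The shortfall is smaller than the spread of the genes, an allowance that was not in that rule, so the hour of harvest stays open. The genotype is a biological explanation that the design names and that 1 library per genotype leaves untested.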

How the results depend on the processing

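The alternative that required an authors' lower bound above 0 was chosen after seeing the data; the others were fixed before. The majority direction of some results turned, as given below. Totals are given in the order hho2-1 against Col-0, phr1 against Col-0, hho2phr1 against Col-0, hho2phr1 against phr1, and hho2phr1 against hho2-1, where the reported totals were 179, 274, 390, 225 and 406. They became 495, 709, 1090, 716 and 1655 at 1.5-fold, 63, 75 (37 higher and 38 lower in place of 157 and 117), 96, 76 and 84 at 4-fold, 292, 440, 641, 365 and 750 with a pseudocount of 0.1, and 62, 101, 153, 78 and 149 with one of 5, as thresholds and shrinkage dictate. With intervals apart they were 35, 130, 224, 78 and 231. With FPKM of at least 5 they were 91, 169, 265, 128 and 270, and with a lower bound above 0 they were 71, 174, 279, 120 and 290, fewer genes being compared. The overlap for the phr1 allele, 102, became 163 and 41 with pseudocounts of 0.1 and 5 and stayed between 74 and 102 otherwise. That for the hho2 allele, 42 (23 higher and 19 lower), became 65 and 16 (7 and 9) with those pseudocounts, 23 (11 and 12) with FPKM of at least 5, 23 with a lower bound above 0 and 14 with intervals apart. The departure count, 386, became 759 and 142 with those pseudocounts, 228 with FPKM of at least 5 and 219 with a lower bound above 0.

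For limma the reported counts were 48 for phr1, 8 for hho2 and 1 for the third split. Without a filter on low values all 3 were 0 (limma; unadjusted 1411 higher and 1006 lower for phr1, 563 and 579 for hho2, 755 and 510 for the third split). For this and the other limma changes the cause was not tested. Rescaled to equal sums they were 13, 5 and 15, with 5 higher and 8 lower for phr1 in place of 31 and 17, and 8 and 7 for the third split in place of 0 and 1. The unadjusted limma numbers for hho2 became 894 higher and 251 lower in place of 480 and 483. This setting shifts the median of all genes by up to -0.10. Without a trend phr1 gave 10, and with a pseudocount of 0.1 it gave 73. With FPKM of at least 5, hho2 gave 4. With a lower bound above 0, phr1 gave 104, hho2 gave 1 and the third split 0 (limma; unadjusted 781 higher and 441 lower).

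Removing the filter could not change the counts of the 5 comparisons, since a 2-fold difference at a pseudocount of 1 needs an FPKM of at least 1. Equal sums turned the majority of the 2-fold genes in hho2phr1 against hho2-1 from 259 higher and 147 lower to 209 and 215, as did the 1.5-fold threshold (776 and 879). They turned that of hho2-1 against Col-0 from 85 and 94 to 96 and 88 (147 and 145 with a pseudocount of 0.1), that of the departure from 203 and 183 to 192 and 198 (370 and 389 with a pseudocount of 0.1), and lowered the share higher in the phr1 overlap from 69.6% to 59.4%. Equal sums turned the sign of 15 of 115 list medians, all 15 inside the middle 95%, and the other rescaling turned 0. Either rescaling moved 0 of them by more than the mean of their spread to each side, other pseudocounts moved 2 each, FPKM of at least 5 moved 3 and no filter moved 1. Of 541 differences of named genes, pseudocounts of 0.1 and 5 moved 50 and 42. Against random lists that were not matched, 4 of 115 percentiles came inside the middle 95%. Besides the endodermis and abscisic acid medians given above, these were sulfur in hho2phr1 against hho2-1 (percentile 4.27) and senescence in hho2phr1 against Col-0 (percentile 3.62). With 1 library per genotype, depth limits genes of few fragments most.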

Other observations

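The tests of abscisic acid, of the abundant storage transcripts and of the HEI10 region were chosen only after the results had been seen, and the genes of the next paragraph were chosen after their values were seen, without a test of any shared function.

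The glutathione transferase gene GSTF6 was at 206 and 220 FPKM in Col-0 and hho2-1, and at 475 and 462 in phr1 and hho2phr1 (limma, adjusted p = 0.043). CYP71A12, of indolic defence compounds, was at 38.0 and 38.6 FPKM against 82.0 and 81.7 (limma, adjusted p = 0.039). The glucosyltransferase genes DOGT1 and UGT74E2 were at 13.4 and 5.12 FPKM in Col-0 and at 36.2 and 15.5 in phr1 (limma, adjusted p = 0.030 and 0.046). WRKY46, a transcription factor of defence, was at 3.27 and 3.74 FPKM against 9.32 and 10.2 (limma, adjusted p = 0.047). PR1 did not pass, at an adjusted p of 0.061 in limma, nor did CYP71A13, at 0.10. Since limma called 4 to 79 genes for the phr1 allele in simulated data with no changed gene, passing is weak evidence for any of these genes.

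Seed storage transcripts were higher in both libraries with the hho2 allele, with CRU3 at 28.7 and 40.1 FPKM against 4.84 and 1.02. In phr1 against Col-0, neither of which has that allele, the 11 measured seed transcripts had a median of -0.592, with 1 above 0. Seed transcripts thus also differed without the hho2 allele, and their low level in phr1 enlarges the difference of hho2phr1 from phr1. In hho2phr1 against Col-0 their median was 1.027, with 10 above 0. The median of the abscisic acid list was -0.23 in hho2-1 against Col-0, which argues against an abscisic acid response of the seedlings there, and 0.206 in hho2phr1 against phr1, where that explanation stays open. RNA of seeds or seed remains in the harvested material would bring other abundant storage transcripts. The highest upper bound of CRU2, SESA3, SESA4, SESA5 and OLEO3 was 0.036 times the lower bound of CRU3 in hho2-1 and hho2phr1, which argues against it for these transcripts. Of those seen before, SESA1 was at 2.36 FPKM in hho2-1 against 0.584 in Col-0 and at 2.46 in hho2phr1 against 0.051 in phr1. OLEO1 was at 3.85 against 1.39 and at 3.73 against 0.108, while OLEO4 was lower in both comparisons. Seed remains are thus not excluded. Of 13 seed transcripts not examined before, 2 reached 1 FPKM, too few to decide, with medians of 0.273 and 0.932 where 0.5 had been set for both comparisons, while 10 of 11 measured seed transcripts, most of them seen before, followed the pattern. An effect of the hho2 allele stays open as the biological explanation.

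HEI10 (AT1G53490, chromosome 1, 19963047 to 19969757) was at 30.9 FPKM in Col-0 and at 1.73, 1.4 and 1.38 in hho2-1, phr1 and hho2phr1, and MRD1, on the same interval, was at 10.1 against 0.047, 0.081 and 0.367. If reads of HEI10 had been assigned to MUM4 in the mutants, MUM4 would need 55.4 FPKM, and its highest upper bound, 47.9, lies below that (difference -7.46). That need used the Col-0 values without their intervals, 26.7 to 47.9 for MUM4 and 20.7 to 41 for HEI10. The test thus leaves out part of the spread and does not exclude this explanation. Allele effects that multiply would leave HEI10 at 0.078 FPKM in hho2phr1, and since the authors' lower bound there is 0, this cannot be excluded. A structural difference between the Col-0 plants and the mutant lines at this locus is a candidate explanation: the next expressed genes on both sides, MSL4 and MPK18, differed by at most 0.336. The MRD1 intervals of Col-0 and hho2phr1 overlap, which keeps it open.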
